A study of Mus musculus with 10 samples.

How the data were processed

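Messenger RNA was measured by RNA sequencing in 10 mouse libraries, of macrophages sorted by flow cytometry into cells that had taken up apoptotic cells (Eff+) and cells that had not (Eff-). Per the labels' protocols, 6 libraries came from skin wounds collected 3 days after wounding in LysMCreER/mTmG mice given tamoxifen for 6 days (3 Eff+ and 3 Eff-). The other 4 came from bone marrow cells of wild-type mice grown with GM-CSF for 7 days and given labelled apoptotic fibroblasts for 12 h (2 Eff+ and 2 Eff-). RNA was polyadenylated and was isolated with a column kit, per the labels.

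The deposited values are raw read counts per gene, 1 column per sample. For the in vivo libraries the authors counted reads with featureCounts 1.6.0 at its default settings against the Ensembl release 106 annotation of the GRCm39 mouse genome, per the file headers. That command has no strand option, so reads of a gene and of an antisense neighbour cannot be told apart in these counts. Trimmomatic 0.39 and GRCm39 are named in the submitters' processing notes, and the aligner is not given in the sources used here. The in vitro counts, on the same 55414 gene identifiers, carry no record of the counting command, so its version and strand setting are not given in the sources used here. Another 4 columns of the in vitro table match no sample's labels and were not used here. Gene names came from GENCODE vM21, which named 52081 of the 55414 identifiers, holding 99.91% of counts. Coordinates are those of the in vivo annotation (GRCm39).

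Samples were assigned to groups by their titles. In vitro, the Eff- column names carry the letters NOAC, while the labels of all 4 libraries list the apoptotic fibroblast treatment, so it is unclear whether the Eff- cells had met apoptotic cells. No label says that replicates are separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. In vivo, Lyz2 had 159484 and 345046 counts in the Eff+ and Eff- libraries numbered 2 and 160 to 413 in the other 4. That argues against technical copies of 1 sample for the libraries numbered 2. Interferon-stimulated genes took 1.04 and 0.72% of counts in the Eff+ and Eff- libraries numbered 1. They took 0.34 and 0.33% in those numbered 3. That argues against technical copies of 1 sample for numbers 1 and 3 as well. No pair of replicates agreed within sampling noise, with a chi-square per degree of freedom between 87.8 and 608 over genes.

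Total counts ranged from 39735437 to 57308823 in vivo and from 17622740 to 27261880 in vitro. Each model was fitted alone with edgeR 4.0.16 in R 4.3.3: trimmed mean of M-values (TMM) scaling, filterByExpr, estimated dispersions, and the quasi-likelihood test of Eff+ against Eff- with no covariate. P-values were adjusted by the Benjamini-Hochberg method and genes under 0.05 were called. A standard error (SE) is the log2 fold change divided by the square root of its F statistic. CPM values are those of edgeR's cpm function on the TMM-scaled library sizes, and their means are given with the SD over libraries. For a gene with no count in any library of 1 group, the fold is a lower bound against a floor of 3 counts over that group, which covers counting error only. A fit over all 10 libraries tested whether the difference between Eff+ and Eff- differed between the models. The models share no library.

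The tests, 33 gene lists (713 distinct genes, some in more than 1 list) and the rule for named genes were set before the data were examined. Each list was tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, two-sided, with adjustment over the 33 lists, and again with an estimated correlation and with fry. The rule named the 6 genes of largest change in each direction among called genes with at least 5 CPM and no overlap between groups, up to 4 called members of each list in each direction, and 11 fixed genes. Where fewer than 10 genes were called it named the 5 of smallest p in each direction. Predicted and RIKEN gene models were left out of the first part, and a few genes that the rule names are not reported here. Ratios within an in vitro replicate number were taken after adding 0.5 CPM to both values.

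Alternatives were other scalings (relative log expression, upper quartile, totals only), DESeq2 1.42.0, limma-voom, robust and newer quasi-likelihood settings, other filters, a replicate block, genes of other cell types left out, and each library left out in turn. The newer quasi-likelihood settings, leaving out whole replicate numbers, and upper quartile and totals-only scaling of the lists were chosen after seeing the data. The procedure was tested on simulated counts with 200 changed genes. With 3 libraries per group it called 10% of 2-fold and 59% of 4-fold changes, with 5 unchanged genes called among 14908. With 2 per group it called 0% of either, with 1 unchanged gene called among 14867, and for the difference between models it called 0% of 4-fold changes among 20270 genes. Figures were drawn with matplotlib 3.10.9.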

Results

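Efferocytosis, the uptake of apoptotic cells, was studied in macrophages from skin wounds and in cultured macrophages. Eff+ and Eff- macrophages were sorted from day 3 wounds of LysMCreER/mTmG mice, in which Cre recombination driven from the lysozyme M locus switches a membrane reporter from tdTomato to GFP (3 libraries each, 39735437 to 57308823 counts). Per the labels, Eff+ and Eff- bone marrow derived macrophages, grown with GM-CSF, were sorted after 12 h with labelled apoptotic fibroblasts (2 libraries each, 17622740 to 27261880 counts). The Eff- column names, with the letters NOAC, leave unclear whether the Eff- cells had met apoptotic cells. In vivo libraries had counts in 17575 to 19972 genes. In vitro, the libraries of replicate 2 had counts in 19649 (Eff+) and 18171 (Eff-) genes, and those of replicate 1 in 35649 and 44836.

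The first comparison asked how macrophages that had engulfed apoptotic cells in the wound differed from those that had not. Wound Eff+ macrophages had higher transcript levels of neutrophil-associated, inflammatory, stress and immediate early genes than Eff- macrophages, and lower levels of the complement genes C1qa and C1qb and of lysosomal and respiratory chain genes. The differences of these lists passed with a preset correlation between genes, and none passed with an estimated correlation (smallest adjusted p = 0.47). S100a8 (ENSMUSG00000056054, chromosome 3, 90576285 to 90577342), a subunit of the alarmin calprotectin, was 6.14-fold higher, at 9658 ± 942 CPM against 1574 ± 462 (SD, n = 3 each). Il1b (ENSMUSG00000027398, chromosome 2, 129206490 to 129213059), which encodes interleukin 1 beta, was 2.37-fold higher, at 8306 ± 346 against 3500 ± 706 CPM. C1qa (ENSMUSG00000036887, chromosome 4, 136623228 to 136626114), a chain of the C1q opsonin, was 2.27-fold lower, at 252 ± 37.9 against 573 ± 67.9 CPM. Pltp (ENSMUSG00000017754, chromosome 2, 164681438 to 164699631), a phospholipid transfer protein, was 2.62-fold lower, at 79.3 ± 12.0 against 208 ± 9.11 CPM.

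**Figure D1:**
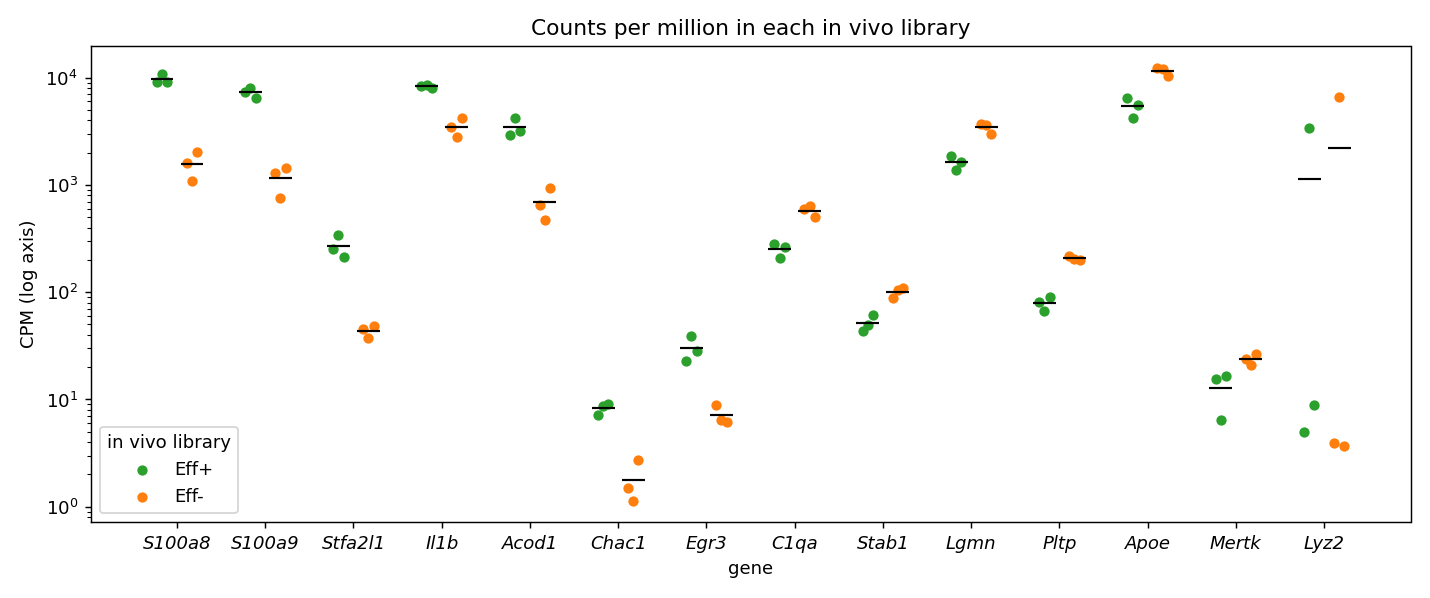
CPM (log axis) of 14 genes in each in vivo library, Eff+ in green and Eff- in orange, with 1 point per library and a line at the mean of 3. S100a8 and Il1b lay higher in every Eff+ library and C1qa and Pltp lower, while Lyz2 was far higher in the libraries numbered 2 than in the other 4.

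The edgeR test called 1666 of 14908 genes, 1101 higher and 565 lower in Eff+ (66.1% higher). With library totals as the only scaling it called 3368, 714 higher and 2654 lower (21.2% higher), with a median log2 fold change of all genes of -0.42 against -0.03. Of the calls 1270 were shared and none changed sign. Under DESeq2 3150 genes were called. Of all tested genes, 5483 (36.8%) had no overlap between the groups, against 10% by chance. Without Eff+ library 2, edgeR called 0 genes (smallest adjusted p = 0.058, with 3260 at an unadjusted p under 0.05), and without both libraries numbered 2 it called 0 (0.20, with 2212), which ended the call of each gene named here as having risen or fallen in vivo. Without Eff- library 1, 2 or 3 there were 451, 189 and 901 calls, and without Eff+ library 3 there were 820.

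Markers of other cell types were among the largest differences. Of 24 tested neutrophil markers 19 rose and none fell (23 rose adjusted over the list alone), with a median log2 fold change of 2.53 (camera, adjusted p = 2.0e-17; adjusted p = 0.47 with an estimated correlation). The list took 5.44, 5.97 and 5.26% of counts in the Eff+ libraries and 1.75, 1.30 and 2.17% in the Eff- libraries. It included S100a9 (log2 fold change 2.64, SE 0.28), the partner of S100a8, Stfa2l1 (2.63, SE 0.23), a stefin, Ngp (3.07, SE 0.49), a granule protein, and Mxd1 (2.06, SE 0.25). Hdc, which makes histamine, rose by 2.62 (SE 0.39). All 29 tested fibroblast markers had positive log2 fold changes (median 1.28, with 0.82 without Eff+ library 3 and 1.93 without Eff- library 2) but only Acta2, smooth muscle actin, at 2.27 (SE 0.26) and Col6a3, a collagen chain, at 2.07 (SE 0.50) rose (camera, adjusted p = 7.1e-07; adjusted p = 0.54 with an estimated correlation). Of 12 tested keratinocyte markers 5 rose (camera, adjusted p = 0.020; adjusted p = 0.51 with an estimated correlation). Krt14, a basal epidermal keratin, had 0 counts in each Eff- library and 10.4, 16.9 and 3.49 CPM in the Eff+ libraries, at least 501-fold higher, and Krt5, at 9.09, 3.00 and 0.56 CPM, at least 206-fold higher (86.9-fold without Eff+ library 1). Of 12 tested muscle and adipocyte markers 3 rose (median 2.12; camera, adjusted p = 0.0017; adjusted p = 0.47 with an estimated correlation), among them the myosin light chain gene Mylpf (1.89, SE 0.31). The other called genes of largest rise were Mgam (3.83, SE 0.58), Krt83 (3.38, SE 0.66), Lypd6b (3.29, SE 0.44) and Hip1r (3.04, SE 0.44).

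In the same libraries, inflammatory and stress genes were higher. Of 26 inflammatory cytokine and enzyme genes 8 rose and none fell (12 rose and 2 fell adjusted over the list alone; camera, adjusted p = 0.0053; adjusted p = 0.51 with an estimated correlation). They included Acod1, which makes itaconate (log2 fold change 2.32, SE 0.30), the chemokine gene Ccl4 (1.94, SE 0.24) and Il12a (2.40, SE 0.37). Of 20 unfolded protein and integrated stress response genes 8 rose and 1 fell (camera, adjusted p = 0.0053; adjusted p = 0.49 with an estimated correlation), with Chac1 at 2.22 (SE 0.39), Sesn2 at 1.77 (SE 0.24) and Ddit3 at 1.44 (SE 0.26). Of 24 immediate early genes, a class that also rises when tissue is dissociated, 8 rose (camera, adjusted p = 0.0017; adjusted p = 0.51 with an estimated correlation), with Egr3 at 2.06 (SE 0.27), Btg2 at 1.65 (SE 0.32) and Dusp1 at 1.22 (SE 0.25). The glycolysis list (median 0.46, camera, adjusted p = 0.0036) and the hypoxia list (median 0.59, camera, adjusted p = 0.020) were also higher, both with adjusted p = 0.73 with an estimated correlation. The glycolysis median was 0.30, 0.26 and 0.73 without Eff- library 1, 2 or 3. It was 0.07 with library totals only and 0.18 without both libraries numbered 2. The hypoxia median was 0.20 with library totals only and 0.32 without both libraries numbered 2. The called members of these lists were Slc16a3, a lactate exporter (1.46, SE 0.34), Pfkfb3 (1.36, SE 0.33) and Kdm3a (1.31, SE 0.25). The hypoxia call ended without Eff+ library 2 or 3 (camera, adjusted p = 0.077 and 0.087) and without Eff- library 1 or 2 (0.099 and 0.067). Neutrophil markers took the larger share of counts in these Eff+ libraries, as given above.

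Apoptotic cell receptor and lysosome genes were lower on balance. Of 21 tested apoptotic cell receptors and bridging proteins 7 fell and 3 rose (11 fell and 4 rose adjusted over the list alone), with a median log2 fold change of -0.88 (-0.09 with no filter on low counts; camera, adjusted p = 0.042; adjusted p = 0.51 with an estimated correlation). C1qb (-1.22, SE 0.22), the scavenger receptor gene Stab1 (-0.96, SE 0.19) and the integrin gene Itgb5 (-0.92, SE 0.20) fell, while the lipid-binding receptor genes Cd300lf (1.47, SE 0.28) and Cd14 (1.10, SE 0.21) rose and C1qc (-1.05, SE 0.38, adjusted p = 0.11) did not pass. As a sum, the list took 3.09, 3.01 and 2.81% of counts in the Eff+ libraries and 2.30, 2.24 and 2.32% in the Eff- libraries, with Cd14 at 23308 against 10890 CPM. That list did not pass without Eff+ library 1 or 2 (camera, adjusted p = 0.071 and 0.065) or without Eff- library 1, 2 or 3 (0.091, 0.098 and 0.051). Its median was -0.53 without Eff+ library 2 and -0.46 and -0.57 without Eff- library 1 or 2. Of 26 engulfment machinery genes 17 had positive values, Rab7, a small GTPase gene of phagosome maturation (1.00, SE 0.19), and Rac2 (0.96, SE 0.24) rose and Elmo2 (-0.82, SE 0.20) fell. The list did not pass (median 0.29, and -0.10 with library totals only, where Rac2 was not called; camera, adjusted p = 0.28). Of 34 lysosome genes 8 fell and 1 rose (camera, adjusted p = 0.00045; adjusted p = 0.47 with an estimated correlation), with the protease gene Lgmn at -1.09 (SE 0.20) and the glycosidase genes Gusb at -0.90 (SE 0.18) and Hexa at -0.78 (SE 0.15). Tfeb, a transcription factor of lysosome biogenesis, rose by 1.40 (SE 0.23) and its relative Tfec was at -1.12 (SE 0.27). Of 29 respiratory chain genes 4 fell and 28 had negative values (camera, adjusted p = 2.9e-06; adjusted p = 0.51 with an estimated correlation), including Cyc1 (-0.69, SE 0.14) and Ndufs3 (-0.84, SE 0.18). The mitochondrial transcripts were lower too (median -0.62; camera, adjusted p = 0.020; adjusted p = 0.73 with an estimated correlation), though not without Eff+ library 3 or Eff- library 2 (0.097 and 0.061). Fatty acid oxidation genes (median -0.43; camera, adjusted p = 0.0047; adjusted p = 0.49 with an estimated correlation), of which Etfa fell by 0.81 (SE 0.15), and MHC class II genes (median -1.07; camera, adjusted p = 0.0036; adjusted p = 0.62 with an estimated correlation), of which Ifi30 fell by 1.07 (SE 0.22), were lower. Of 18 LXR target and cholesterol efflux genes 3 fell (camera, adjusted p = 0.034; adjusted p = 0.48 with an estimated correlation), namely Pltp, Nr1h3, which encodes LXR alpha (-1.15, SE 0.22), and Apoe (-1.09, SE 0.23). Beside these falls stood the higher neutrophil share of counts in the same libraries.

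Of 24 alternative activation genes 4 rose and 7 fell, and the list did not pass (camera, adjusted p = 0.10). The formyl peptide receptor gene Fpr2 (1.96, SE 0.21) and Pdcd1lg2 (1.68, SE 0.25) rose, and Ccl24 (-1.36, SE 0.21) and the lectin gene Clec10a (-1.17, SE 0.19) fell. Among macrophage identity genes, which did not pass as a list (camera, adjusted p = 0.92), Cd33 rose by 2.02 (SE 0.28) while Maf and Adgre1, a macrophage surface receptor gene, were at -1.15 (SE 0.25) and -0.85 (SE 0.20). The lower genes of largest change were Flywch1, Galnt9, Utp20, Vwa8, Tmem221 and AW209491, each at least 2.98-fold lower. Of the fixed genes, the efferocytosis receptor genes Mertk (-0.88, SE 0.34, adjusted p = 0.13) and Axl (-0.57, SE 0.28, adjusted p = 0.22) did not pass, nor did Abca1 (-0.33), Arg1 (-1.14), Col1a1 (1.28) or Mfge8 (0.21, and -0.16 with library totals only). Timd4 was too low to be tested. Lyz2, the gene of the lysozyme M locus, differed within both groups, with 220, 159484 and 413 counts in Eff+ libraries 1, 2 and 3 and 198, 345046 and 160 in Eff- libraries. Its near-identical neighbour Lyz1 had 25107, 8409 and 15430 counts in the Eff+ libraries and 58658, 25266 and 28804 in the Eff- libraries. Reads split between them are uncertain. The sum of both genes was 167893 and 370312 in the libraries numbered 2 against 15843 to 58856 in the other 4. The zygosity of the Cre allele is not given in the sources used here. In all, 16 of 33 lists passed in vivo, 9 higher and 7 lower, and 17 did not (adjusted p = 0.053 to 0.96); with an estimated correlation none passed, the smallest adjusted p being 0.47, and fry called 7, of which 6 were among the 16 and the other was alternative activation. For the cholesterol biosynthesis, arginine, dendritic cell and T and NK cell lists, which did not pass in vivo, the median differed in sign from the mean or the test.

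**Figure D2:**
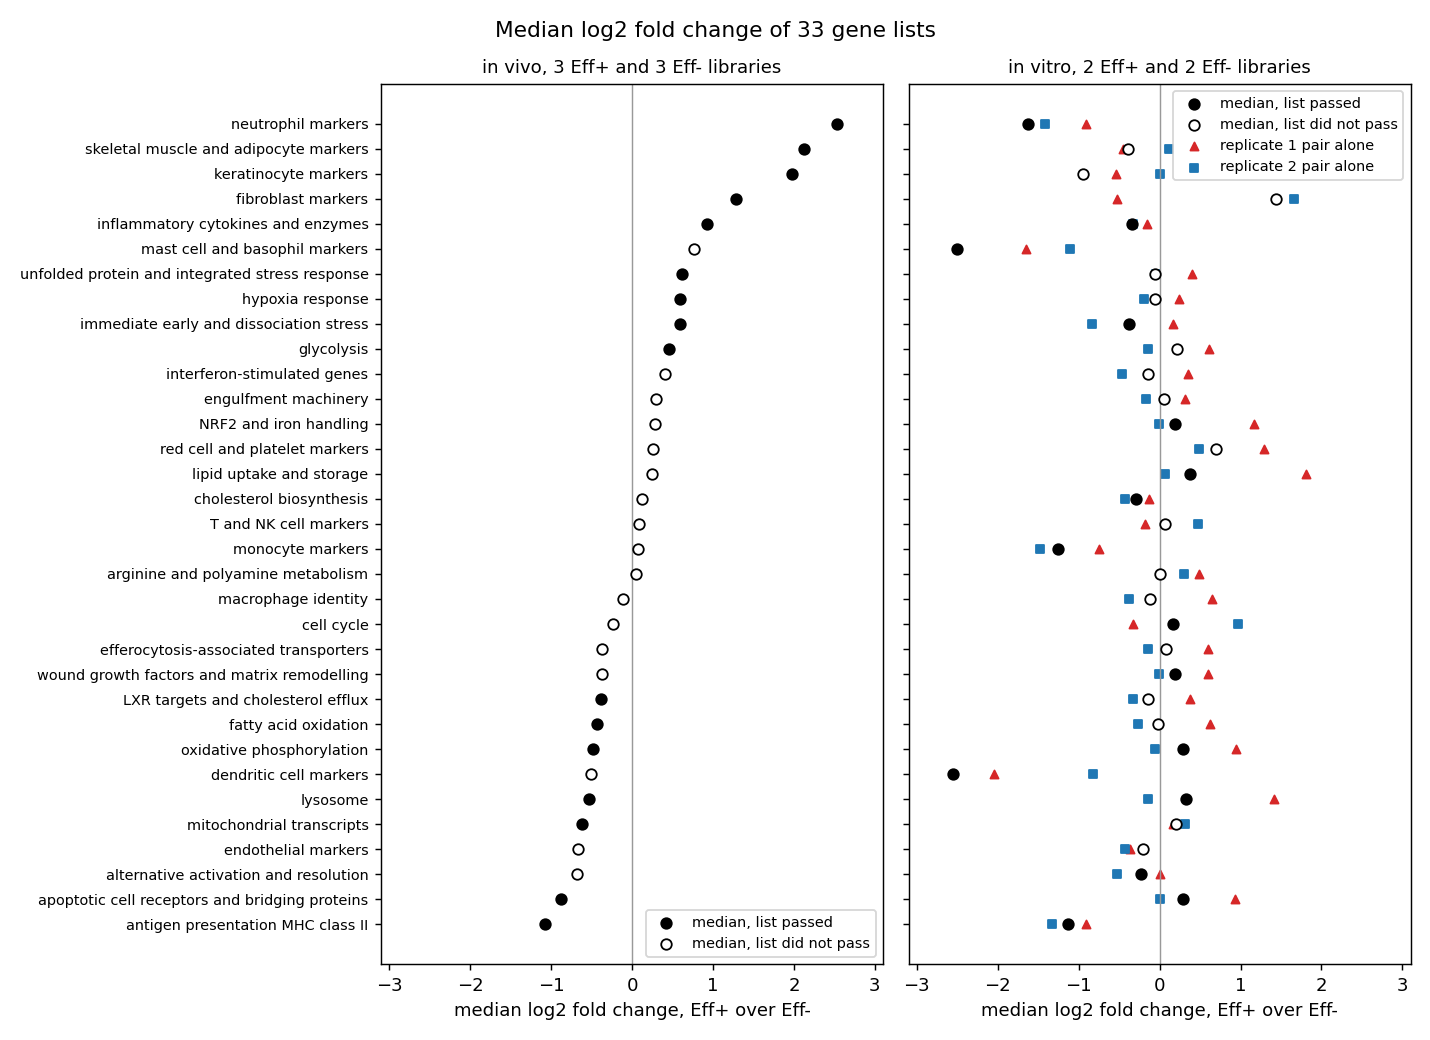
Median log2 fold change, Eff+ over Eff-, of 33 gene lists in vivo (left) and in vitro (right), filled where the list passed camera with a preset correlation, and with the medians of the replicate 1 pair (red) and the replicate 2 pair (blue) alone in vitro. The neutrophil list had the highest median in vivo (2.53) and a negative one in vitro (-1.62).

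The second comparison asked the same of cultured macrophages, although it is unclear whether the Eff- cells there had met apoptotic fibroblasts. No gene passed the edgeR test without a replicate block, so the differences are given as values only. Il1b (log2 fold change -2.67, SE 0.40) was at 7.78 and 6.06 CPM in the Eff+ libraries against 42.9 and 45.5 in the Eff- libraries, and the chemokine gene Ccl5 (-2.55, SE 0.48) at 3.70 and 4.11 against 27.5 and 18.1. S1pr1, a sphingosine phosphate receptor gene (1.89, SE 0.49), was at 38.1 and 47.8 against 8.03 and 15.1, and the adhesion gene Flrt2 (2.28, SE 0.57) at 57.9 and 26.2 against 6.91 and 10.3. The edgeR test called 0 of 14867 genes (smallest adjusted p = 1.0), 115 had an unadjusted p under 0.05 against 743 by chance, and DESeq2 called 2, Il1b and Cacnb3 (adjusted p = 0.0031 each), both lower in Eff+. Groups did not overlap for 20.7% of genes, against 33.3% by chance. Both chance figures assume independent libraries, while same-numbered libraries deviated from their group means together (correlation 0.74). The calls were 25 without Eff+ library 1 and 27 without Eff- library 2. With a library left out in culture, here and for the lists, 1 group is a single library that is assumed to vary like the other group. With the replicate number as a block, although no label pairs the numbers, 802 genes had an unadjusted p under 0.05. That edgeR test called 48, 9 higher and 39 lower in Eff+. Il1b and Ccl5 were among the lower and S1pr1 and Flrt2 among the higher. It called 6 genes of the dendritic cell list and 3 of the MHC class II list, all lower.

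Within replicate numbers, the 2 pairs had little in common across genes (Pearson's r = 0.065 over 14867 genes, which are not independent, with 47.2% of the same sign). Genes of small p with the same sign in both pairs, given as replicate 1 then replicate 2 log2 ratios, were Jaml (-2.38, -1.68), Cacnb3 (-4.57, -3.07), Bmf (-1.81, -1.68), Lyzl4 (2.90, 1.65) and Gm8818 (2.04, 1.40). Among the fixed genes, the cholesterol exporter gene Abca1 (1.97, 0.88) and the bridging protein gene Mfge8 (1.81, 1.06) were higher in both pairs. Arg1 (2.02, 0.32) was also higher, S100a8 (-0.28, -0.85) and Axl (-0.30, -0.68) were lower in both, and Mertk (1.58, -0.14), Lyz2 (2.14, -0.37) and Col1a1 (-0.23, 2.48) went both ways. Chosen after their values were seen, the migratory dendritic cell genes Ccr7 (-3.76, -5.33), Ccl22 (-3.51, -5.52) and Fscn1 (-5.09, -1.25) were lower and Cd36, a scavenger receptor gene (1.97, 1.71), higher in both pairs.

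**Figure D3:**
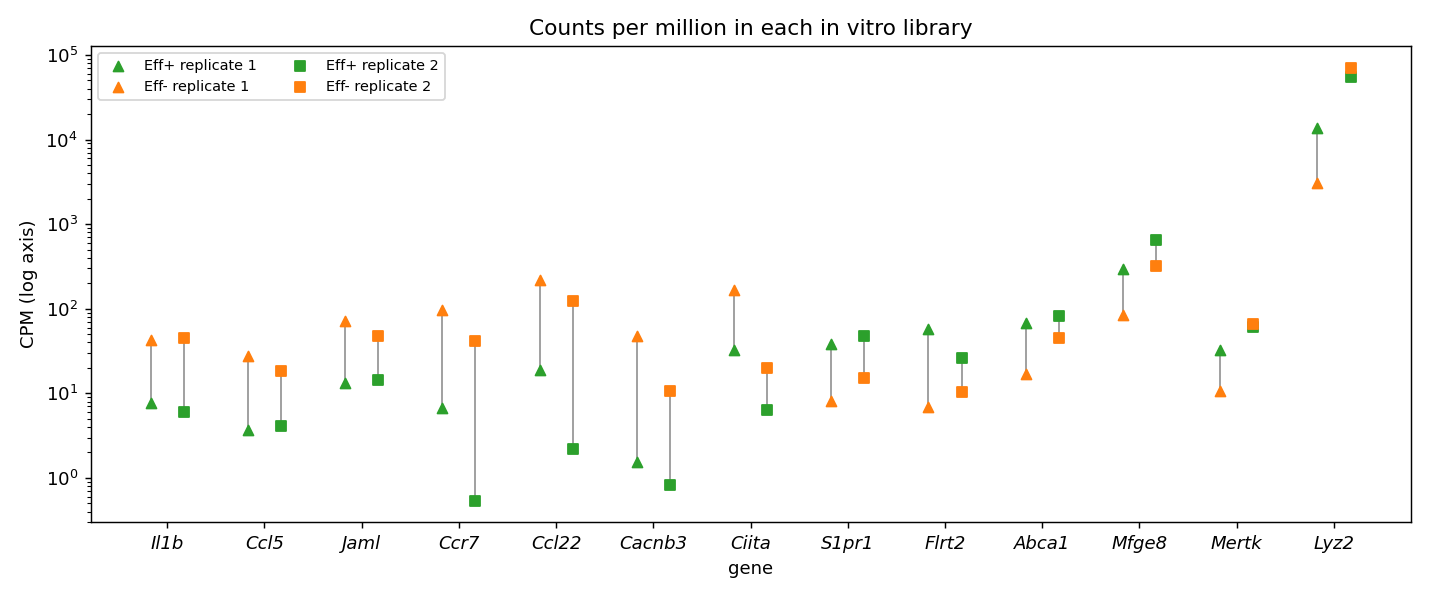
CPM (log axis) of 13 genes in each in vitro library, Eff+ in green and Eff- in orange, replicate 1 as triangles and replicate 2 as squares, each pair joined by a line. Il1b was lower in Eff+ in both pairs (7.78 and 6.06 against 42.9 and 45.5 CPM), while Mertk and Lyz2 differed in direction between the pairs.

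Among the lists in vitro 16 passed, 7 higher and 9 lower, and 17 did not (adjusted p = 0.14 to 0.98). None passed with an estimated correlation (smallest adjusted p = 0.72) or with fry (0.63). By median, dendritic cell, MHC class II, monocyte and neutrophil lists were lower in both pairs. Macrophage identity genes had medians of 0.65 and -0.37 in replicates 1 and 2. As a sum, neutrophil markers took 0.227 and 0.306% of counts in Eff+ libraries 1 and 2 against 0.217 and 0.361% in Eff-. That sum was not lower in replicate 1, while the dendritic cell, MHC class II and monocyte sums were lower in both pairs. Dendritic cell markers had a median of -2.55 (camera, adjusted p = 2.8e-09; adjusted p = 0.72 with an estimated correlation), and -2.04 and -0.82 in replicates 1 and 2, with 13 of 17 genes lower in both; without Eff- library 1 the median was -0.40 and without Eff+ library 2 -1.64. MHC class II genes had a median of -1.13 (camera, adjusted p = 4.4e-07; adjusted p = 0.72 with an estimated correlation), and 11 of 13 were lower in both pairs; without Eff- library 1 it was -0.49. Monocyte markers (median -1.25; camera, adjusted p = 4.5e-11; adjusted p = 0.72 with an estimated correlation) and neutrophil markers (median -1.62; camera, adjusted p = 5.9e-11; adjusted p = 0.72 with an estimated correlation) were lower in both pairs for 11 of 18 and 15 of 19 genes. The monocyte median was -0.41 without Eff- library 2, and the neutrophil median was -4.64 without Eff+ library 1 and -0.85 without Eff+ library 2. All 6 tested mast cell markers were lower in both pairs (median -2.51; camera, adjusted p = 0.00027; adjusted p = 0.72 with an estimated correlation), but without Eff- library 1 the list did not pass (0.44) and its median was 0.57, and without Eff+ library 2 it was -1.17. The lysosome list was higher (median 0.33; camera, adjusted p = 0.00015; adjusted p = 0.73 with an estimated correlation), at 1.42 in replicate 1 and -0.14 in replicate 2. Respiratory chain genes (median 0.28; camera, adjusted p = 8.7e-05; adjusted p = 0.72 with an estimated correlation) were at 0.94 and -0.06, and without Eff- library 1 the lysosome and respiratory chain medians turned to -0.27 and -0.25 (camera, adjusted p = 0.011 and 0.12), against 2.08 and 1.57 without Eff- library 2. They were 0.60 and 0.54 without Eff+ library 1 and 0.13 and 0.093 without Eff+ library 2. The other lists that passed were higher for apoptotic cell receptors (median 0.29), lipid uptake (0.37), NRF2 and iron handling (0.19), wound growth factors (0.19) and cell cycle (0.17, and -0.04 with library totals only). They were lower for cholesterol biosynthesis (-0.29), inflammatory (-0.34), immediate early (-0.38) and alternative activation genes (-0.24). Their camera adjusted p lay between 0.0017 and 0.034, and each had adjusted p = 0.72 with an estimated correlation. As sums, the inflammatory and alternative activation lists took more counts in Eff+ in both pairs. The inflammatory list took 0.313 and 0.217% against 0.237 and 0.199%, and alternative activation 0.290 and 0.438% against 0.169 and 0.358%. The cholesterol biosynthesis sum was lower in both pairs, and the immediate early sum went both ways. Without Eff- library 1 the direction of the test turned for the apoptotic cell receptor, lipid and NRF2 lists (camera, adjusted p = 0.50, 0.50 and 0.89) and the wound growth factor list did not pass (0.89). Without Eff- library 2 it turned for the cholesterol, immediate early, alternative activation and cell cycle lists (0.038, 0.023, 0.083 and 0.99) and the inflammatory list did not pass (0.52). Without Eff+ library 1 the cholesterol list turned (0.11) and the alternative activation and immediate early lists did not pass (0.37 and 0.30), nor did the receptor list without Eff+ library 2 (0.099). Without Eff+ library 1, Eff+ library 2, Eff- library 1 and Eff- library 2 in turn, the median was 0.28, -0.19, -0.0070 and 0.89 for receptors. It was 0.58, 0.012, 0.0058 and 2.07 for lipid uptake, and 0.38, 0.24, -0.093 and 1.62 for NRF2 genes. In the same order it was 0.38, 0.13, 0.31 and 1.05 for wound growth factors, 0.24, 0.26, 0.98 and 0.11 for cell cycle and 0.21, -0.95, -0.65 and 0.95 for cholesterol biosynthesis. It was -0.39, -0.15, -0.076 and -0.31 for inflammatory, -0.34, -0.83, -1.09 and 1.17 for immediate early and -0.60, -0.17, -0.17 and 0.11 for alternative activation genes. Fibroblast markers, of the engulfed cell type, did not pass (median 1.44, adjusted p = 0.66) and were at -0.52 and 1.66. The median differed in sign from the test for the LXR, fatty acid oxidation, stress response, arginine and macrophage identity lists, which did not pass. The higher gene number of replicate 1 stood beside all of these differences between pairs.

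The last comparison asked whether the difference between Eff+ and Eff- macrophages itself differed between wound and culture. As it is unclear whether the culture Eff- cells had met apoptotic cells, the wound and culture contrasts may not be alike. Il1b had the smallest p, with a log2 fold change of 1.25 in the wound and -2.67 in culture, a difference of 3.94 (SE 0.55, adjusted p = 0.10) that did not pass. Other genes higher in the wound contrast were Nfe2, a haematopoietic transcription factor gene (4.01, SE 0.57), the coagulation factor gene F5 (3.04, SE 0.44), Cmah (3.95, SE 0.58) and Slc22a15 (4.34, SE 0.64), and the lower ones were Cd276 (-3.49, SE 0.64), Slc12a7 (-2.25, SE 0.44), the neuropilin gene Nrp1 (-2.29, SE 0.45), Mdfic (-1.89, SE 0.38) and Myo5a (-1.82, SE 0.37), none of which passed (adjusted p = 0.10 to 0.14). The edgeR test called 0 of 20270 genes, 2222 had an unadjusted p under 0.05, and limma-voom called 0. Without in vitro Eff- library 2 it called 2009, without in vitro Eff+ library 1 it called 7, and without in vitro Eff- library 1 it called 4.

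Across the 13091 genes tested in both models, which are not independent, log2 fold changes correlated at Pearson's r = -0.25 and Spearman's rho = -0.26. Of 1529 genes called in the wound and tested in culture, 427 (27.9%) had the same sign in culture. Without in vitro Eff- library 1, Pearson's r was 0.12. No gene was called in both models by edgeR in the same or the opposite direction, as none was called in culture, where 115 had an unadjusted p under 0.05, and DESeq2 gave 1 in opposite directions.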

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

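The tests of these opposite signs, of library scaling, of dilution and of other splits were chosen after the results were seen, while the second neutrophil list was fixed before its values were. For 6 lists the difference between Eff+ and Eff- passed in both models with opposite signs, and the difference between the models, tested with camera over all 10 libraries, passed for 5. Apoptotic cell receptors had medians of -0.88 in the wound and 0.29 in culture, and their difference did not pass (adjusted p = 0.075). Neutrophil markers had medians of 2.53 in the wound and -1.62 in culture (camera, adjusted p = 1.51e-17, and 0.34 with an estimated correlation). As a sum, they took 0.227 and 0.306% of counts in culture Eff+ against 0.217 and 0.361% in Eff-, so that sum was not lower in replicate 1. Of the 26 listed genes, 5 are also in another list and 15 reached 1 CPM in the cultured macrophages. Respiratory chain genes had -0.49 and 0.28 (adjusted p = 7.18e-09; 0.63 with an estimated correlation), and lysosome genes -0.54 and 0.33 (adjusted p = 8.97e-07; 0.63 with an estimated correlation). Inflammatory genes had 0.93 (1.44 without wound Eff- library 3) and -0.34 (camera, adjusted p = 0.000119, and 0.58 with an estimated correlation). As a sum, that list took more counts in culture Eff+ in both pairs, at 0.313 and 0.217% against 0.237 and 0.199% in Eff-. Immediate early genes had 0.59 and -0.38 (camera, adjusted p = 0.000592, and 0.63 with an estimated correlation). The culture medians moved with single libraries. Without in vitro Eff- library 1 those of the respiratory chain and lysosome lists were -0.25 and -0.27, the sign of the wound. In the replicate 2 pair they were -0.06 and -0.14. The immediate early median was 1.17 without in vitro Eff- library 2 and 0.17 in the replicate 1 pair. Neutrophil and inflammatory medians stayed negative with each in vitro library left out. The test between models was not repeated with a library left out. No group had the 4 samples a test for outlying samples needs.

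Higher neutrophil genes with lower macrophage genes in the wound Eff+ libraries may come from neutrophils, or RNA of neutrophils, in the sorted cells. For the higher neutrophil genes, scaling of the libraries was argued against by their median, which was at least 2.141 under 4 scalings. Across these scalings the median of all genes lay between -0.42 and 0.007. A shift of that size could not have removed the neutrophil difference, so the outcome was nearly fixed in advance. The lower macrophage genes were not tested in this way. A second neutrophil list that shares no gene with the first lay 2.06 above the median of all genes, all 24 genes positive and 17 called, the most abundant being Slpi (5825 against 1373 CPM) and Ccrl2 (3632 against 1347), although 23 of the 24 also reached 1 CPM in the cultured macrophages. Dilution of macrophage RNA by neutrophil RNA cannot be told apart from a change in the macrophages. The spread of 27 macrophage genes beyond their errors, 0.3374, lay between the bounds set for either. Of the 27, 26 were negative, with Spp1 (0.74) the exception. As 21 of the 27 are also in a fixed list, their signs largely restate the falls given above. The fixed macrophage identity list had 11 positive and 12 negative values, so not all macrophage genes were lower. Uptake of apoptotic cells, which the design gives as the difference between the groups, stays open and untested, as does the sorting gate, and the type of cell taken up in the wound is not identified here.

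Among the 10 splits of the 6 wound libraries into 3 and 3, the real split alone (1) gave as many genes, with 1666 against at most 0 in the others. For gene lists 3 of the 10 splits gave as many, the real split with 16 and the highest other also with 16. With 10 splits a share under 0.05 cannot be reached.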

How the results depend on the processing

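Leaving out whole replicate numbers, the newer quasi-likelihood settings, and upper quartile and totals-only scaling of the lists were chosen after seeing the data. The cause of each change below was not tested, except that fewer libraries were fitted where some were left out. Of 1666 genes called in vivo, totals-only scaling gave 3368, DESeq2 3150, a fold of at least 2 1043, leaving out both libraries numbered 2 gave 0, and leaving out each library in turn 0 to 1347; the other settings, except the replicate block, stayed within 1.5 times. Of 0 called in vitro, DESeq2 and no filter gave 2 each, leaving out each library 0 to 27. Of 0 in the difference between models, leaving out the in vitro libraries numbered 1 gave 7, and each library in turn 0 to 2009. Genes called in opposite directions in both models numbered 1 with DESeq2 and 0 to 4 with a library left out, those in the same direction 0 to 2, and the correlation ranged from -0.31 to 0.12. Against 16 lists in vivo an estimated correlation gave 0 and fry 7, of which 6 were among the 16, with 23 for fry in mixed directions; against 16 in vitro an estimated correlation, fry and fry in mixed directions gave 0, and leaving out each library gave 14 to 25.

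The replicate number was added as a block although no label says what the numbers share. Same-numbered samples deviated together in vivo at correlations of 0.247, -0.011 and 0.133, and not every one correlated best with its own number. In vitro both were 0.74. Some traits did go by number in vivo. Lyz2 had 159484 and 345046 counts in the libraries numbered 2 and 160 to 413 in the others. Interferon-stimulated genes took 1.04 and 0.72% of counts in the libraries numbered 1 and 0.27 to 0.34% in the others. A pairing by number therefore stays possible, and the main test ignores it. With the replicate block 2985 genes were called in vivo and 441 in the difference. In vitro 48 were called, 9 higher and 39 lower in Eff+, with Il1b, Ccl5, S1pr1 and Flrt2 among them. Between the models 4 were called in the same direction and 13 in opposite directions (4.1 and 4.7 for independent lists). In each model 18 lists passed. Of 86 named genes in vivo, 4 that had not passed were called with the block.

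With each library left out, the adjusted p in vitro ranged from 7.19e-09 to 0.50 for apoptotic cell receptors, 3.32e-33 to 0.011 for lysosome, 1.24e-11 to 0.11 for cholesterol biosynthesis, 1.44e-14 to 0.50 for lipid uptake, 9.88e-18 to 0.12 for the respiratory chain, 0.00019 to 0.37 for alternative activation, 3.38e-13 to 0.89 for NRF2, 3.20e-11 to 0.30 for immediate early and 9.16e-15 to 0.99 for cell cycle, with the direction turned in each. Log2 fold changes that changed sign were, in vivo, Mfge8 (-0.16 with totals only, -0.059 to 0.43 with a library left out) and Lyz2 (0.17 with limma-voom, 0.17 with the replicate block, 0.87 without libraries numbered 2, -8.30 to 8.19). In vitro, with a library left out, they were Ciita (-3.85 to 0.025), H2-Ob (-6.31 to 0.078), Col1a1 (-3.65 to 6.03, and -0.28 without libraries numbered 2), S100a8 (-1.17 to 0.44), Axl (-0.78 to 0.15), Mertk (-0.48 to 2.42, and -0.13 without libraries numbered 1) and Lyz2 (-1.46 to 3.77, 0.84 with limma-voom, 0.88 with the replicate block, 2.21 without libraries numbered 2). Of 86 named genes in vivo 84 kept their sign under every setting, and of 23 in vitro 16 did. All 16 lists called in vivo kept their direction, but 2 did not pass with totals only and 3 did not pass without both libraries numbered 2. With totals only, where the median of all genes was -0.42, the in vivo medians moved to -0.93 for lysosome, -0.88 for the respiratory chain, -1.04 for mitochondrial, -0.82 for fatty acid oxidation, -0.76 for LXR, 0.54 for inflammatory, 0.22 for stress response and 0.21 for immediate early genes. In vitro the inflammatory median was -0.56 with totals only and -0.15 with no filter, alternative activation -0.0074 with no filter, and mast cell markers -1.47 with a minimum of 1 CPM. In simulated counts 59% of 4-fold changes were called in vivo and 0% in vitro, at biological coefficients of variation of 46.9 and 69.7%; what depth, sample number and this spread each contribute was not tested.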

Other observations

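Some lipid and antioxidant genes differed in the wound although their lists did not pass. Of 21 lipid uptake and storage genes 4 rose and 1 fell (camera, adjusted p = 0.19), with the triglyceride synthesis genes Dgat2 and Dgat1 at log2 fold changes of 2.11 (SE 0.30) and 2.00 (SE 0.29) and the lipid receptor gene Trem2 at -1.11 (SE 0.19). Of 24 NRF2 and iron genes 4 rose and 2 fell (camera, adjusted p = 0.28), with Gsr, glutathione reductase, at 1.83 (SE 0.28), the cystine transporter gene Slc7a11 at 1.78 (SE 0.36) and Nfe2l2, which encodes NRF2, at 1.02 (SE 0.17). Arg2, an arginase, rose by 1.54 (SE 0.21) among arginine and polyamine genes that did not pass as a list (camera, adjusted p = 0.91). Neutrophil markers took 5.44, 5.97 and 5.26% of counts in these Eff+ libraries against 1.75, 1.30 and 2.17% in Eff-. Each of these calls ended without Eff+ library 2 (edgeR, smallest adjusted p = 0.058).

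The test of exon length on the replicate 1 libraries and the second dendritic list were fixed before their results were seen, and the depth and left-out library tests after. The replicate 1 libraries in vitro had counts in more genes. Greater depth was argued against by the totals, 24707347 (Eff+) and 17622740 (Eff-) in replicate 1 against 27261880 and 22921618 in replicate 2. Thinned to the lowest total, the replicate 1 libraries still had at least 1.767 times the genes of replicate 2. With lower totals in replicate 1, that thinning could hardly have come out otherwise. Low-level reads spread over the genome are a candidate explanation. Of 34200 genes at 0 in both replicate 2 libraries, 15701 (Eff+) and 24156 (Eff-) had a count, with medians of 2 and 3. Counts followed exon length with Spearman's rho of 0.5296 and 0.67 across genes. The correlation was not computed for a library without the excess of genes. Low expression can also follow exon length, so the correlation cannot separate such reads from it. No biological explanation was tested.

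Dendritic cell genes were lower in culture Eff+. A single outlying library stays open: without Eff- library 1 the median was -0.4031, against -3.21, -1.64 and -3.38 without each of the others, but the replicate 2 pair, which does not hold that library, was at -0.82, and 13 of 17 genes were lower in both pairs. More mature dendritic-like cells among the Eff- cells cannot be told apart from it, as a second list of mature dendritic genes had medians of -1.09 and -0.5121 in the replicate pairs, between the bounds set for either outcome, with 20 of 24 genes negative. All but a few of those genes also reached 1 CPM in wound Eff- macrophages (21 of 26).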
